A study of Mus musculus with 36 samples.

How the data were processed

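RNA was measured by single-end sequencing (75 bp reads) in 36 libraries of mouse bone marrow-derived macrophages. The cells had been grown for 7 days from bone marrow on non-adherent plates in RPMI medium with 10% fetal calf serum and 10% L929 cell supernatant, which supplies the growth factor M-CSF. They carried either the wild-type Tnip2 gene (WT) or the D310N form of it, and were left unstimulated (0 min) or given 100 ng/ml lipopolysaccharide (LPS) for 30, 60, 120, 240 or 360 min. Each of the 12 groups of genotype and time held 3 libraries. The sample titles write the mutation as D310N and the header of the table writes D309N; the name of the titles is used.

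Per the submitters' processing notes, reads were aligned to mm10 with STAR 2.5.2a, quantified per gene with RSEM 1.2.31 and normalised with DESeq2 1.10.1. The deposited table holds normalised values on a log2 scale for 16439 genes, from -4.14 to 19.3, and no raw counts. The notes do not name the transformation that gave these log2 values, and a transformation that pulls low values together would make the log2 differences of weakly expressed genes too small. Read depth per library is unknown, so neither counting intervals nor detection limits are given. Library medians of the deposited log2 values ranged from 6.83 to 7.2.

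Of the 16439 genes, 23 whose names had been turned into calendar dates were left out, which left 16416. A gene was tested when its value was at least 10 on the linear scale, 3.32 on the log2 scale, in at least 3 libraries, and 11656 genes passed. Positions are on GRCm38 (mm10) from GENCODE mouse release M21, matched by gene symbol, with older symbols matched through the RefSeq gene table. A position was found for 11567 of the tested genes (99.2%). Overlapping genes, pseudogenes and near-identical family members are uncertain, since the counting is not stated to use strand or to resolve shared reads.

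Genes were tested with limma 3.58.1 in R 4.3.3 on the log2 values as deposited, with 1 mean per group over all 36 libraries, so that all comparisons shared 1 estimate of the spread with 24 residual degrees of freedom and an intensity trend in the empirical Bayes step. Comparisons were D310N against WT at each of the 6 times and on average over them, each LPS time against 0 min within each genotype, and the difference of these LPS responses between the genotypes, at each of 5 times and jointly by an F test. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. A difference of log2 values is given with its standard error (SE). The plan had foreseen log2(value + 1) of a linear table; because the table was already on a log scale, no pseudocount was added, and pseudocounts of 0.5, 1 and 8 on the back-transformed values were tried instead.

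Gene lists were compared with all other tested genes by limma's camera test with a preset correlation of 0.01 between members, adjusted over the lists within a comparison, and again with the correlation estimated for each list. Of 29 lists, 27 had at least 3 tested members; the table held 0 mitochondrially encoded transcripts, and the erythroid, megakaryocyte and mast cell list had 2 tested members. The comparisons, filter, lists, main model and rule for naming genes were chosen before the data were examined. That rule names Tnip2 and 5 genes of its pathway; the 5 largest rises and 5 largest falls between genotypes at each time without overlap of the libraries, and the 10 largest of each on average; the 3 largest rises and falls under LPS in WT at each time; the 10 genes with the smallest joint p for a different time course; up to 4 members of each list, the most changed first; and sex-linked genes. The largest rises and falls, between genotypes and under LPS, needed a mean of at least 50 on the linear scale in the higher group. This is 5.64 on the log2 scale. The other parts of the rule set no such floor. Some genes that this rule names are not reported here.

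The model was tested on simulated data built on the comparison at 0 min with 11656 genes. It recovered 44%, 76%, 96% and 100% of 50 genes changed by 0.25, 0.5, 1 and 2 on the log2 scale, with 9 false calls among 11431 unchanged genes. A simulated list of 25 genes shifted by 0.3 was called (adjusted p = 1.82e-38), and 0 of 20 random lists were. The simulated genes varied independently of each other, so this cannot show how the list test behaves where members move together.

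The replicate numbers 1 to 3 recur in every group. Whether they pair the libraries was checked by the correlation of same-numbered libraries' deviations from their group means. Among the comparisons checked, all 3 pairs exceeded 0.1 only for D310N at 120 min against 0 min (0.131 to 0.373), from the data and not from the labels. Pairing elsewhere is not excluded. Over all pairs of times, D310N libraries sharing number 1, 2 or 3 correlated by a mean of 0.208, 0.284 and 0.0697, against -0.0931 for different numbers. The main model treats all libraries as separate, so its p-values for the average over the times may be too small. The replicates are not stated to be separate animals or separate cultures, so the p-values measure only the spread between the samples as deposited.

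Alternatives were quantile normalisation, trimmed mean scaling, library weights, a robust empirical Bayes step, fits of only the libraries compared, other filters, the pseudocounts above, the replicate number as a block or as a correlated effect, and leaving out each library in turn. Added after the data were seen were fits without 4 libraries that stand apart, a block of replicate number within genotype, a comparison of 3 against 3 means over the time course, and list tests under quantile normalisation and without the library labelled WT at 360 min, replicate 1. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for reading, permutation tests and plots.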

Results

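Tnip2 encodes ABIN-2, a protein that binds and stabilises the kinase Tpl2 and carries a ubiquitin-binding motif. The D310N change lies in that motif. The comparisons ask how LPS-treated macrophages that carry this form differ in RNA from WT macrophages, before LPS and along the response to it. Values are log2 differences ± SE from limma with n = 3 libraries per group. Positive values are higher in D310N or after LPS.

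The Tnip2 RNA itself (chromosome 5, 34496087 to 34513991) lay close together in both genotypes. Its group means ± SD on the log2 scale, D310N and then WT, were 8.87 ± 0.02 and 8.82 ± 0.05 at 0 min, 9.05 ± 0.02 and 9.04 ± 0.02 at 30 min, and 9.17 ± 0.03 and 9.09 ± 0.06 at 60 min. Later they were 9.09 ± 0.05 and 9.10 ± 0.09 at 120 min, 9.34 ± 0.04 and 9.15 ± 0.17 at 240 min, and 9.08 ± 0.03 and 9.25 ± 0.14 at 360 min. The Tnip2 difference passed at 240 min alone (0.18 ± 0.06, adjusted p = 0.0398). This call is lost when any of 5 of the 6 libraries of that time is left out. Without WT replicate 1 or 3 the difference is 0.16 or 0.11, and without D310N replicate 1, 2 or 3 it is 0.17, 0.18 or 0.20. At 360 min Tnip2 gave -0.17 ± 0.06 (adjusted p = 0.0563). It passed without WT replicate 1 (-0.21, adjusted p = 0.0335) or 3 (-0.22, adjusted p = 0.0221), with adjusted p-values of 0.0221 to 0.397 over all alternatives. LPS raised Tnip2 in WT by 0.28 to 0.43 between 60 and 360 min. The joint test of a different time course gave an adjusted p of 0.145. Because the mutation changes a single codon, the level of the Tnip2 RNA checks nothing about the genotype labels.

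Of the 5 genes of the same pathway fixed for report, Tnfaip3, which encodes the NF-kB inhibitor A20, was lower in D310N at 360 min (-0.24 ± 0.06, adjusted p = 0.0033). Its LPS time course passed the joint test (adjusted p = 0.0424), but this call is lost when any of 24 of the 36 libraries is left out, with an adjusted p of up to 0.0949. Map3k8, which encodes Tpl2, was lower at 120 min (-0.21 ± 0.05, adjusted p = 0.0033). Tnip1, which encodes the related protein ABIN-1, was higher at 120 min (0.18 ± 0.06, adjusted p = 0.024). Without WT replicate 1 or 2 or D310N replicate 1 or 2 of that time its adjusted p is 0.076, 0.0891, 0.0666 or 0.0571, and with trimmed mean scaling it is 0.0526, in a range of 0.000335 to 0.0891 over all alternatives. Tnip3, an LPS-induced member of the family, gave -0.13 ± 0.09 at 360 min (adjusted p = 0.353). Without the library labelled WT at 360 min, replicate 1, it gave -0.32 (adjusted p = 0.00076, the lowest of a range to 0.772 over all alternatives). Nfkb1, which encodes the precursor p105 that holds Tpl2, differed by at most 0.08 in size at any time with all libraries and was not called. With library weights it was called at 0 min (-0.07, adjusted p = 0.0309 in a range to 0.662 over all alternatives) and 60 min (0.07, adjusted p = 0.035 in a range to 0.388). Its LPS response at 360 min was called without the library labelled WT at 360 min, replicate 1 (0.16, adjusted p = 0.045, the lowest of a range to 0.716).

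LPS changed 710 of 11656 genes in WT at 30 min (558 up, 152 down), 4335 at 60 min (2341 up, 1994 down) and 7761 at 120 min (3772 up, 3989 down). The counts were 9321 at 240 min (4612 up, 4709 down) and 9367 at 360 min (4584 up, 4783 down; 9366 without replicate 1 of that time). Quantile normalisation moves the early split towards falls, to 599 up and 620 down of 1219 genes at 30 min and 1870 up and 3424 down of 5294 genes at 60 min. Among the genes changed most were Egr1, an immediate early transcription factor (5.16 ± 0.16 at 30 min), and the neutrophil-attracting chemokine genes Cxcl2 (3.92 ± 0.19) and Cxcl1 (3.85 ± 0.24) at the same time. At 60 min they included the cytokine genes Lif (4.94 ± 0.25), Tnfsf9 (4.87 ± 0.09) and Csf2 (4.80 ± 0.15), and later Ifnb1, which encodes interferon beta (5.16 ± 0.22 at 120 min). At 240 min the serpin gene Serpina3g (7.36 ± 0.15), the T cell chemokine gene Cxcl9 (6.83 ± 0.06) and Nos2, the inducible nitric oxide synthase (6.68 ± 0.07), rose most. Falls included Arrdc3, an arrestin-domain gene (-4.08 ± 0.17 at 120 min), and the cannabinoid receptor gene Cnr2 (-4.27 ± 0.13 at 240 min). At 360 min Plekhg3 (-3.67 ± 0.11) and the chemokine receptor gene Cxcr4 (-3.56 ± 0.15) were among them. All of these passed with adjusted p-values of 5.8e-14 (Cxcl1 at 30 min) or lower.

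The fixed lists of LPS-induced genes rose in WT in an order of times. Of 25 immediate early and ERK-dependent genes, 23 rose and 0 fell at 30 min, with a median of 2.64, and 21 rose and 2 fell at 60 min. The counts adjusted over the list alone are the same, and Nr4a1 (3.59 ± 0.17) and Ier2 (3.36 ± 0.15) at 30 min are examples. Early inflammatory cytokines rose in 10, 15, 16, 17 and 17 of 17 genes from 30 to 360 min (17 at 120 min adjusted over the list alone), among them Tnf (3.34 ± 0.12 at 30 min) and Il6 (6.16 ± 0.14 at 240 min). Chemokines rose in 10, 18, 18, 18 and 18 of 19, among them Ccl5 (5.54 ± 0.08 at 240 min). Type I interferon-stimulated genes rose in 19 of 40 at 60 min (3 fell; 19 and 4 adjusted over the list alone). They rose in 40 of 40 at 120, 240 and 360 min, with medians of 1.41, 3.31 and 3.20, as in the antiviral genes Rsad2 (5.24 ± 0.07) and Gbp5 (5.66 ± 0.05) at 240 min. The list test at 60 min for these interferon genes is lost with an estimated correlation (adjusted p = 0.385). Those at 120, 240 and 360 min hold (adjusted p = 0.0112, 0.0187 and 0.018). Interferon-gamma type and antigen presentation genes rose in 20, 22 and 22 of 22 at these times, among them Cd40 (5.02 ± 0.05 at 240 min). NF-kB inhibitors and feedback regulators rose in 12 to 14 of 16 genes at every LPS time, with Nfkbia (2.89 ± 0.05) and Nfkbiz (3.30 ± 0.07) already up at 30 min. Cytokine signalling feedback genes rose in 14 of 15 at 240 min, with Socs3 at 3.78 ± 0.07.

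Other lists went down or both ways under LPS in WT. Cell cycle and proliferation genes fell in 16, 21 and 21 of 25 at 120, 240 and 360 min (17 at 120 min adjusted over the list alone), with medians of -0.35, -1.33 and -1.84. Examples are Mcm2, part of the replication helicase (-2.03 ± 0.08 at 240 min), and Rrm2, which makes DNA precursors (-2.85 ± 0.10 at 360 min). With an estimated correlation these calls are lost (adjusted p = 0.612, 0.309 and 0.231), though that at 360 min passes without the library labelled WT at 360 min, replicate 1 (0.0224). Of 23 resident macrophage identity genes, the regulator gene Cebpa (-3.80 ± 0.09 at 240 min) and the receptor gene Cx3cr1 (-2.25 ± 0.10 at 240 min) fell, while Fcgr1 rose (1.75 ± 0.08 at 240 min). Mitochondrial oxidative phosphorylation genes rose in 21 of 23 at 240 min (median 0.33, estimated-correlation adjusted p = 0.343) and cytosolic ribosomal protein genes in 23 of 28 (median 0.20, estimated-correlation adjusted p = 0.708). The direction of the ribosomal median at that time, and of the mitochondrial median at 120 and 360 min, flips under quantile normalisation.

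In D310N, LPS changed 774 genes at 30 min (601 up, 173 down), 4489 at 60 min (2480 up, 2009 down) and 7461 at 120 min (3718 up, 3743 down). Later it changed 9224 at 240 min (4541 up, 4683 down) and 9325 at 360 min (4550 up, 4775 down). Quantile normalisation gives 562 up and 510 down of 1072 genes at 30 min, 1927 up and 3472 down of 5399 at 60 min and 3013 up and 4661 down of 7674 at 120 min. The genes called in both genotypes numbered 547, 3677, 6759, 8549 and 8617 from 30 to 360 min. Of them 0, 1, 7, 9 and 10 went opposite ways. Those called in the same direction numbered 3676, 6752, 8540 and 8607 from 60 to 360 min. Independent calls would give 842, 2484, 3689 and 3749 genes called in the same direction. Across all tested genes, which are not independent of each other, the LPS changes of both genotypes correlated with r = 0.872, 0.959, 0.971, 0.982 and 0.981 at the 5 times. The slope of D310N on WT, fitted only over the genes called in either genotype at that time, was 0.989, 0.982, 0.956, 0.956 and 0.981. The LPS responses of Tnf, Il6, Il1b and Nfkbia, 4 genes that NF-kB induces, were not called different between genotypes (joint adjusted p = 0.896, 0.542, 0.146 and 0.134). Without the library labelled WT at 360 min, replicate 1, Il6 passes (0.0209) and the other 3 do not (Tnf 0.476, Il1b 0.118 and Nfkbia 0.119). Those of the NF-kB regulator genes Bcl3, Nfkbid and Tnfaip3 passed (0.000717, 0.0256 and 0.0424). The calls of Nfkbid and Tnfaip3 are lost without any of 3 and 24 single libraries (adjusted p up to 0.0961 and 0.0949).

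**Figure D1:**
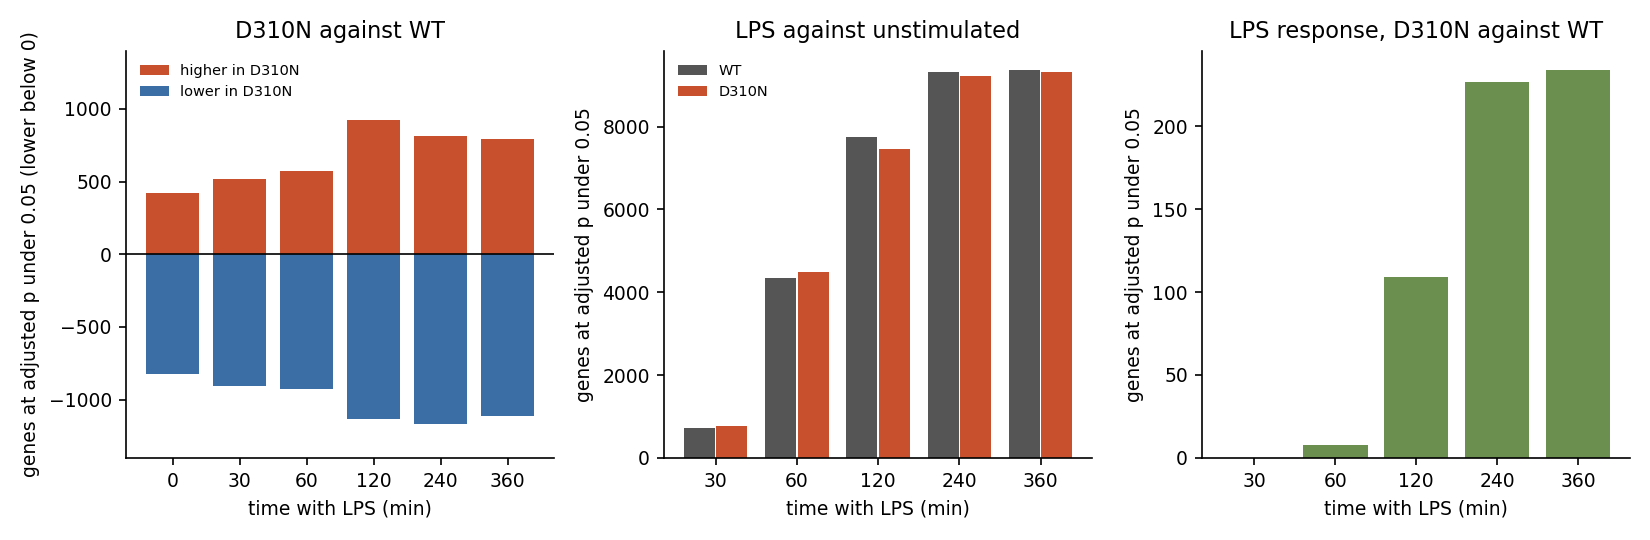
Genes called (adjusted p under 0.05, limma, n = 3 per group) by time after LPS: D310N against WT (1250 at 0 min to 2058 at 120 min), LPS against 0 min in each genotype, and LPS responses that differ between genotypes (0 at 30 min to 234 at 360 min).

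Between genotypes, 1250 genes differed before LPS (424 higher and 826 lower in D310N). The counts were 1423 at 30 min (516 higher, 907 lower), 1498 at 60 min (570 and 928) and 2058 at 120 min (925 and 1133; 642 and 1355 with trimmed mean scaling). They were 1980 at 240 min (814 and 1166) and 1903 at 360 min (793 and 1110), where a fit of the 6 libraries of that time alone calls 12 (5 and 7). Most differences were small: 46, 49, 56, 52, 33 and 28 genes in the order of the times passed with over 1 on the log2 scale in size. Of the genes called, 1234, 1397, 1487, 1934, 1891 and 1524 had no overlap between the 3 libraries of each genotype. Among all tested genes this share was 32.7%, 33.4%, 37.4%, 31.7%, 37.6% and 22.2%, where chance gives 10%. On average over the 6 times 5604 genes differed (2646 higher, 2958 lower), 17 of them by over 1. Called at all 6 times were 302 genes, 86 higher and 215 lower throughout. Taking 1 mean per replicate number and genotype, 3 against 3, gives 3830 genes (1721 higher, 2109 lower). The counts per time lean on single libraries. At 0 min 716 or 753 genes are called without D310N replicate 1 or 3, and at 30 min 932, 861 or 904 without WT replicate 1 or D310N replicate 1 or 3. Without D310N replicate 1 at 60 min 986 are called, without D310N replicate 1 or 3 at 240 min 1190 or 1293, and without D310N replicate 1 or 3 at 360 min 1115 or 1180.

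Some large differences between genotypes were present before LPS and at each later time, whereas others, as that of Dtd1 (below), were small before LPS and grew after it. Mid1, which encodes a microtubule-associated ubiquitin ligase (chromosome X, 169685199 to 170005736), was lower in D310N by -1.84 ± 0.12 at 0 min (adjusted p = 8.6e-12) and -2.16 ± 0.05 on average (adjusted p = 9.6e-25). The noncoding RNA G530011O06Rik, which lies within Mid1 on the other strand, was lower by -2.03 ± 0.10 and -2.61 ± 0.04 (adjusted p = 1.4e-15 and 2.9e-30). Both differences grew after LPS, by -1.26 at 240 min for G530011O06Rik (adjusted p = 2.64e-06) and by -0.78 for Mid1 (adjusted p = 0.0155; up to 0.067 without D310N replicate 1 at 0 min or 3 at 240 min). Whether the counting told reads of these overlapping genes apart is not stated. Fn1, which encodes the matrix protein fibronectin, was higher by 1.27 ± 0.16 at 0 min and 1.40 ± 0.07 on average (adjusted p = 1.9e-06 and 7.4e-17). Itgax, the integrin CD11c of myeloid cells, was higher by 1.13 ± 0.13 and 1.19 ± 0.05. F7, coagulation factor VII, was higher by 1.31 ± 0.26 and 1.33 ± 0.10, and Ptprn, a receptor phosphatase of secretory granules, by 1.30 ± 0.20 and 1.27 ± 0.08. Atp6v0d2, a proton pump subunit of osteoclasts and macrophages, was higher by 0.97 ± 0.06 on average, and Abhd1, a hydrolase gene on chromosome 5 (30950066 to 30955091), by 2.25 ± 0.14 at 0 min (adjusted p = 2.8e-12). Lower on average were Phgdh, the first enzyme of serine synthesis (-1.16 ± 0.05), Ly6a, the surface protein Sca-1 (-1.17 ± 0.07), and Clec4n, the receptor Dectin-2 (-0.99 ± 0.07).

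Type I interferon-stimulated genes were lower in D310N before LPS and in its first 2 h. At 0, 30, 60 and 120 min 33, 38, 39 and 37 of 40 were lower and 0 higher (37, 39, 39 and 39 lower adjusted over the list alone), with medians of -0.31, -0.45, -0.44 and -0.43. Irf7, a transcription factor that amplifies interferon production, gave -0.67 ± 0.11 at 0 min and -0.83 ± 0.11 at 60 min (adjusted p = 8.1e-05 and 3e-06). Ifit3, which binds foreign RNA, gave -0.59 ± 0.07 and -0.77 ± 0.07 (adjusted p = 1.4e-06 and 1.2e-08) at these times, and Isg20, an antiviral exonuclease, -0.54 ± 0.09 at 0 min and -0.82 ± 0.09 at 120 min (adjusted p = 9e-05 and 1.2e-07). The list tests of these 4 times hold with an estimated correlation (adjusted p = 0.0489, 0.00665, 0.00717 and 0.0204), but that at 0 min is lost without the library labelled WT at 360 min, replicate 1 (0.0508). At 240 min 13 were lower (16 adjusted over the list alone; median -0.14), a list call that is lost with an estimated correlation (adjusted p = 0.347). At 360 min 4 were lower (3 adjusted over the list alone; median -0.07), with the list not called. On average over the times 40 of 40 were lower, also adjusted over the list alone, with a median of -0.31 and an adjusted p = 0.0366 with an estimated correlation, a call lost without that library (0.0724). The change in this difference from 0 to 360 min, a median of 0.26 with 9 genes up (23 adjusted over the list alone), passed with the preset correlation and not with an estimated one (adjusted p = 0.0819).

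**Figure D2:**
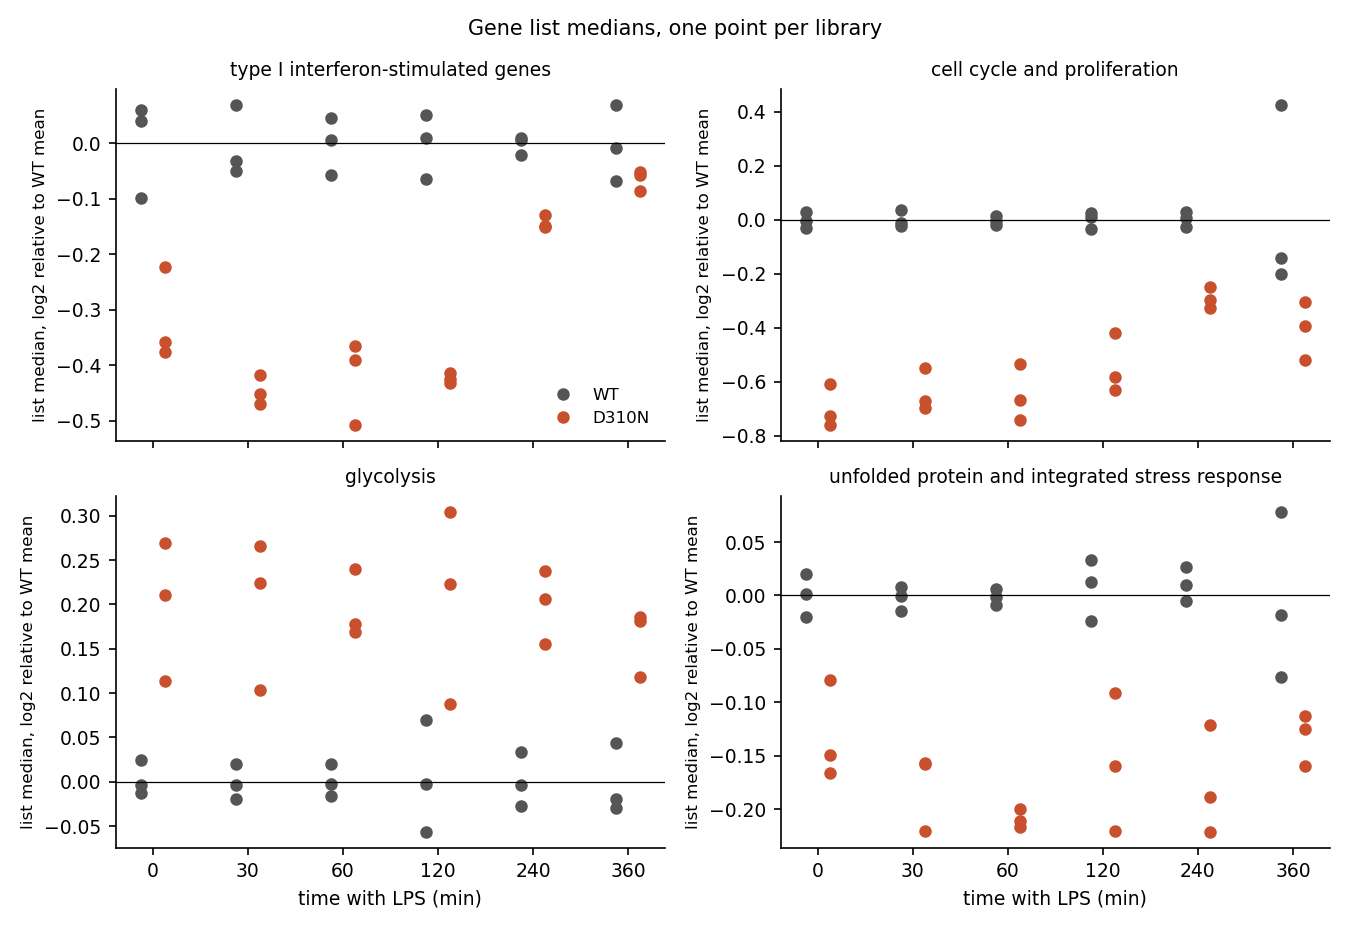
Median log2 value of each list's genes in every library, relative to the WT mean, by time after LPS; interferon-stimulated genes were lower in D310N at 0 min (median difference -0.31), cell cycle genes lower (-0.72) and glycolysis genes higher (0.20).

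Cell cycle and proliferation genes were lower in D310N at 0 min in 19 of 25 and higher in 0 (21 lower adjusted over the list alone), with a median of -0.72. Ccnb1 and Ccnb2, cyclins of mitosis, gave -1.15 ± 0.09 and -1.09 ± 0.14 (adjusted p = 1.7e-10 and 1.6e-06) and the mitotic kinase gene Plk1 -1.01 ± 0.15 (adjusted p = 1.7e-05). Kif18b, a kinesin of dividing cells outside the list, gave -1.26 ± 0.12. At 30, 60, 120, 240 and 360 min 17, 15, 17, 8 and 13 were lower (20, 19, 21, 13 and 18 adjusted over the list alone), with medians of -0.65, -0.65, -0.58, -0.31 and -0.43. On average 22 were lower and 1 higher, with a median of -0.53. With an estimated correlation the list calls at the 6 times and on average are lost (adjusted p = 0.0546, 0.0955, 0.0857, 0.103, 0.397, 0.253 and 0.103). Without the library labelled WT at 360 min, replicate 1, the estimated-correlation values at 0, 30, 60 and 120 min and on average are 0.00106, 0.00301, 0.0038, 0.00922 and 0.0139. At 360 min 8 genes are then lower and 1 higher, with a median of -0.13.

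Glycolysis genes were higher in D310N, 13 of 18 on average and 1 lower (14 and 2 adjusted over the list alone), with a median of 0.19. This list call is lost with an estimated correlation (adjusted p = 0.0819). Gpi1, the isomerase of glucose phosphate, was higher by 0.33 ± 0.02 and Pfkl, the liver-type phosphofructokinase, by 0.39 ± 0.03, and Slc2a1, the glucose transporter GLUT1, by 0.34 ± 0.04 (adjusted p = 8.7e-14, 7e-12 and 5.4e-09). At the single times 10, 12, 10, 12, 11 and 7 were higher (13, 13, 13, 12, 13 and 12 adjusted over the list alone). With an estimated correlation these list calls are lost (adjusted p = 0.0516, 0.0661, 0.0501, 0.154, 0.227 and 0.235). Genes of the unfolded protein and integrated stress response were lower, 16 of 17 on average and 0 higher, with the same count adjusted over the list alone. Their median was -0.16, with an adjusted p = 0.0157 with an estimated correlation. Asns, which makes asparagine, was lower by -0.55 ± 0.04, Chac1, which degrades glutathione, by -1.02 ± 0.09 and Trib3, a pseudokinase, by -0.72 ± 0.06 (adjusted p = 1.3e-12, 3.4e-11 and 1.7e-11), targets of the factor ATF4. At the single times 4, 7, 10, 6, 7 and 6 were lower (6, 11, 11, 7, 13 and 9 adjusted over the list alone). Their adjusted p-values with an estimated correlation are 0.0516, 0.0147, 0.00717, 0.0212, 0.0396 and 0.151, so that the calls at 0 and 360 min are lost. That at 240 min is lost without the library labelled WT at 360 min, replicate 1 (0.0688).

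Interferon-gamma type and antigen presentation genes were lower in D310N on average in 18 of 22 and higher in 0, with the same count adjusted over the list alone and a median of -0.17. The list call is lost with an estimated correlation (adjusted p = 0.0819). H2-D1, a class I histocompatibility gene, was lower by -0.27 ± 0.02, Ciita, the activator of class II genes, by -0.32 ± 0.04, and the costimulator gene Cd86 by -0.38 ± 0.05 (adjusted p = 1.7e-11, 3.2e-08 and 1.2e-07). At the single times 10, 11, 10, 13, 13 and 9 were lower (12, 12, 12, 14, 16 and 11 adjusted over the list alone; estimated-correlation adjusted p = 0.249, 0.187, 0.107, 0.0705, 0.22 and 0.235). Of 21 inflammasome and cell death genes, 9 were lower and 1 higher at 240 min (12 and 1 adjusted over the list alone), with a median of -0.17 and an adjusted p = 0.0396 with an estimated correlation. This call is lost without the library labelled WT at 360 min, replicate 1 (0.165). On average 10 were lower and 1 higher, also adjusted over the list alone, where the call is lost (adjusted p = 0.0934 with an estimated correlation). Mlkl, the executor of necroptosis, was lower by -0.27 ± 0.03 on average, Casp4, the sensor of intracellular LPS, by -0.22 ± 0.02, and Bcl2l11, which encodes the death factor Bim, by -0.24 ± 0.03.

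Chemokine genes diverged at 60 min, where 10 of 19 were lower in D310N and 1 higher (12 and 1 adjusted over the list alone), with a median of -0.30 and an adjusted p = 0.0247 with an estimated correlation. Cxcl10, an interferon-inducible chemokine, gave -0.63 ± 0.08, Ccl12 -0.59 ± 0.08 and Ccl17 -0.63 ± 0.13 at 60 min (adjusted p = 5.9e-07, 5e-06 and 0.00074), and Cxcl11 -0.98 ± 0.07 at 120 min (adjusted p = 2.2e-11). Ccl6, which is made without stimulation, was higher by 0.66 ± 0.11 at 0 min and 0.58 ± 0.04 on average (adjusted p = 5.7e-05 and 2.7e-12). On average 10 were lower and 4 higher (11 and 4 adjusted over the list alone; estimated-correlation adjusted p = 0.26). Early inflammatory cytokines had 4 of 17 lower and 0 higher at 60 min, also adjusted over the list alone (estimated-correlation adjusted p = 0.277). On average 9 were lower and 4 higher (10 and 4 adjusted over the list alone). Il10, the cytokine that restrains macrophages, was lower at 240 min (-0.93 ± 0.17, adjusted p = 0.00028), and so was Ebi3, a subunit of the cytokine IL-27 (-0.60 ± 0.09, adjusted p = 1.8e-05). Il23a, the p19 subunit of IL-23, was higher at 120 min (1.06 ± 0.20, adjusted p = 0.00033) and 240 min (0.97 ± 0.20, adjusted p = 0.0012). Ifnb1 was lower at 60 min (-0.99 ± 0.22, adjusted p = 0.0016). The LPS time courses of Il10 and Ifnb1 were not called different (joint adjusted p = 0.304 and 0.454), but both pass without the library labelled WT at 360 min, replicate 1 (0.00514 and 0.00327). That of Il23a passed (0.0339), a call lost when any of 15 of the 36 libraries is left out, with an adjusted p of up to 0.0732.

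Of 25 immediate early and ERK-dependent genes, 7 were higher and 1 lower in D310N at 0 min, also adjusted over the list alone, with a median of 0.10. The list call is lost with an estimated correlation (adjusted p = 0.0516). Egr2, a transcription factor of the early growth response family, was higher before LPS by 1.07 ± 0.10 (adjusted p = 1.1e-08) and Fosl1, a partner of Jun, by 0.76 ± 0.18 (adjusted p = 0.0035). Jun was lower at 120 min (-0.47 ± 0.06, adjusted p = 2.9e-06). The phosphatase gene Dusp5 (-0.52 ± 0.10) and Myc, a driver of growth (-0.48 ± 0.09), were lower at 240 min (adjusted p = 0.00044 and 0.00061). At that time 5 list members were lower and 1 higher (10 and 2 adjusted over the list alone; estimated-correlation adjusted p = 0.243). On average 7 were higher and 7 lower, with the same counts adjusted over the list alone. Transcription factors of the secondary response had 7 of 24 lower and 1 higher at 120 min (8 and 1 adjusted over the list alone), with a median of -0.10 and an adjusted p = 0.0212 with an estimated correlation, a call lost without the library labelled WT at 360 min, replicate 1 (0.0534). On average 10 were lower and 4 higher, also adjusted over the list alone. Bach1, a repressor that senses heme, was lower at 120 min (-0.72 ± 0.07, adjusted p = 1.1e-08) and Klf4 at 240 min (-0.83 ± 0.11, adjusted p = 6.7e-06).

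The lists of the NF-kB pathway were not called on average. NF-kB inhibitors and feedback regulators had 4 of 16 higher and 2 lower, and their average median of 0.00 changes sign with the scaling. At 120 min 5 were higher (7 adjusted over the list alone), and the list call is lost with an estimated correlation (adjusted p = 0.111). Nfkbid, a nuclear IkB protein, was higher by 0.29 ± 0.04 on average, and Bcl3, another of that family, was lower at 360 min (-0.51 ± 0.08). NF-kB subunits and upstream kinases had 1 of 16 higher, Ikbkg, which encodes NEMO (0.19 ± 0.02), and 4 lower. The TLR4 receptor and adaptors had 3 of 15 higher and 6 lower, among them Tlr4 (-0.15 ± 0.03). Adjusted over the list alone the average counts of these 3 lists are the same. Cytokine signalling feedback genes had 5 of 15 lower and 0 higher at 120 min (6 adjusted over the list alone), and the list call is lost with an estimated correlation (adjusted p = 0.103). On average 5 were lower and 1 higher, also adjusted over the list alone. Il18bp, which neutralises IL-18, was lower by -0.43 ± 0.04. Prostaglandin, nitric oxide and oxidant enzymes had 6 of 20 higher and 7 lower, also adjusted over the list alone. Slc7a11, the cystine transporter, was higher by 0.51 ± 0.06, Alox5, which starts leukotriene synthesis, lower by -0.87 ± 0.06, and Nos2 lower at 120 min by -0.53 ± 0.07 (adjusted p = 7.4e-08, 2e-13 and 1e-06).

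Among the lists of cell state, alternative activation genes had 2 of 13 higher and 6 lower on average. Clec7a, the beta-glucan receptor Dectin-1, was higher by 0.62 ± 0.04 and Clec10a, a lectin, lower by -0.79 ± 0.05 (adjusted p = 2.3e-14 and 1.1e-13). Resident macrophage identity genes had 7 of 23 higher and 10 lower, with Cx3cr1 at 0.35 ± 0.04 and Itgam at 0.21 ± 0.02. Cholesterol synthesis and LXR targets had 6 of 21 higher and 2 lower, mitochondrial oxidative phosphorylation 5 of 23 and 2, and heat shock and handling stress 3 of 9 and 0. Adjusted over the list alone these counts are the same, and none of these 5 lists was called on average. The cholesterol list was called at 360 min (9 higher, 0 lower; 11 and 1 adjusted over the list alone), with Nr1h3, which encodes LXR alpha, at 0.47 ± 0.10. The mitochondrial list was called at 0 and 30 min (1 and 2 higher; 0 and 1 adjusted over the list alone). These 3 calls are lost with an estimated correlation (adjusted p = 0.227, 0.419 and 0.412). Lysosome and autophagy genes had 5 of 23 higher and 9 lower on average (5 and 10 adjusted over the list alone), such as the cathepsin gene Ctsl (0.28 ± 0.03) and Grn, which encodes progranulin (-0.27 ± 0.03). The list call at 240 min (3 higher, 9 lower; 3 and 10 adjusted over the list alone) is lost with an estimated correlation (adjusted p = 0.227). Cytosolic ribosomal protein genes had 19 of 28 higher and 0 lower (21 adjusted over the list alone), with a median of 0.06 and Rps4x at 0.11 ± 0.01. This list call is lost likewise (adjusted p = 0.461 with an estimated correlation).

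Lists of other cell types hold genes that macrophages also express in part. Neutrophil genes were higher in 4 of 6 on average (median 0.30), among them the collagenase gene Mmp8 (0.57 ± 0.04), and stromal genes in 5 of 6 (median 0.37), a list that holds Fn1. Adjusted over the list alone these counts are the same, and with an estimated correlation both list calls are lost (adjusted p = 0.0819 and 0.0946). At 120 min 2 neutrophil genes were higher (4 adjusted over the list alone), with a median of 0.44 and an adjusted p = 0.0442 with an estimated correlation, a call lost without the library labelled WT at 360 min, replicate 1 (0.0534). Dendritic cell genes, which include Itgax, had 3 of 8 higher and 3 lower, with a median whose sign changes with the scaling, and lymphocyte genes 1 of 3 higher and 2 lower. Neither list was called. Of the erythroid, megakaryocyte and mast cell list, Kit, the receptor of stem cell factor, was lower by -0.78 ± 0.08 and Pf4, a platelet chemokine, higher by 0.21 ± 0.04 on average. Mmp9, a gelatinase, was higher by 0.86 ± 0.09. Of 4 sex-linked check genes tested, 0 were higher and 1 lower on average (Uty, -0.10 ± 0.03), with the same counts adjusted over the list alone. Over all 36 libraries Xist lay between -3.39 and -3.02 and Ddx3y between 10.2 and 10.6.

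The LPS response itself differed between genotypes for 0 genes at 30 min by limma (108 at an unadjusted p under 0.05; 1 without D310N replicate 2 at 0 min), and for 8 at 60 min (3 larger and 5 smaller in D310N; 6 and 5 without the filter). Here and below, larger and smaller give only the sign of the difference between the log2 LPS changes. For a gene that LPS lowers, a larger response is thus a lesser fall and a smaller response a deeper fall. It differed for 109 at 120 min (53 and 56; 39 and 68 with trimmed mean scaling), 227 at 240 min (116 and 111) and 234 at 360 min (118 and 116; 145 and 94 with trimmed mean scaling). Jointly over the 5 times 564 genes differed. Without the library labelled WT at 360 min, replicate 1, 581 (341 and 240) are called at 360 min and 1218 jointly. Rin2, a regulator of the small GTPase Rab5 (chromosome 2, 145675215 to 145887616), had the smallest joint adjusted p (1.08e-12). Its difference between genotypes was 0.40, 0.41, 0.99, 0.34, -0.12 and -0.03 in the order of the times. Atf3, a transcription factor that damps LPS-induced genes, rose less in D310N at 60 min (-0.64 ± 0.06, adjusted p = 9.8e-08) and 120 min (-0.45, adjusted p = 4.8e-05). Irg1 (Acod1), which makes itaconate, rose less at 60 min (-0.47 ± 0.05, adjusted p = 2.7e-06), and Cxcl9 less at 120 min (-0.84 ± 0.08, adjusted p = 2.7e-07). Dtd1, a deacylase of mischarged tRNA (chromosome 2, 144599897 to 144768758), was higher in D310N by 1.22 at 240 min and 1.43 at 360 min, and its response was larger by 0.89 at 240 min. The response of Depdc5, an inhibitor of mTORC1 that lies near Tnip2 (chromosome 5, 32863701 to 32994236), was larger by 0.40 at 240 min and 0.69 at 360 min. That of Ssfa2 was larger by 0.50 at 120 min, and that of E2f8, a repressor of cell cycle genes, by 0.95. That of Gm5148 was larger by 1.41 at 120 min. G530011O06Rik overlaps Mid1, so that it is uncertain.

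**Figure D3:**
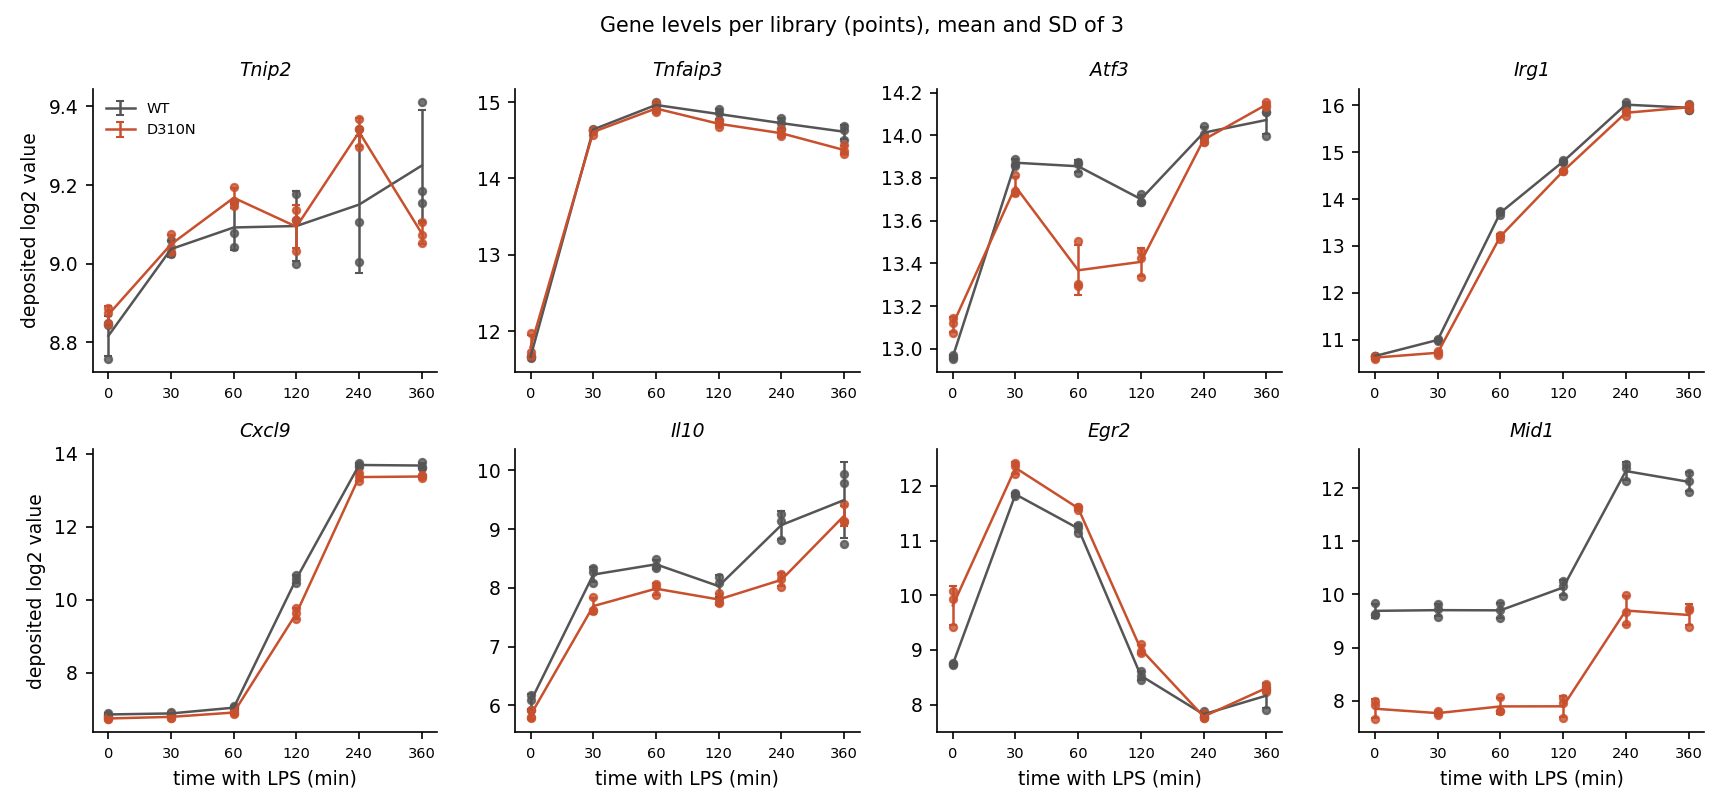
Deposited log2 values of 8 genes by time after LPS, 1 point per library with the mean ± SD of 3: Tnip2, Tnfaip3, Atf3 (response at 60 min -0.64 in D310N relative to WT), Irg1 (-0.47), Cxcl9 (-0.84 at 120 min), Il10, Egr2 and Mid1.

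The counts of differing responses lean on single libraries. At 60 min they are 5, 5 and 5 without WT replicate 1, 2 or 3 of 0 min, and 5 and 4 without WT replicate 2 or 3 of 60 min. They are 5 and 5 without D310N replicate 1 or 3 of 0 min, and 4 and 5 without D310N replicate 1 or 3 of 60 min. At 120 min they are 65 and 56 without WT replicate 1 or 3 of 0 min, and 70 and 69 without WT replicate 1 or 2 of 120 min. They are 56 and 62 without D310N replicate 1 or 3 of 0 min, and 65 without D310N replicate 3 of 120 min. At 240 min they are 125, 111 and 122 without WT replicate 1, 2 or 3 of 0 min, and 110 without WT replicate 1 of 240 min. They are 92 and 98 without D310N replicate 1 or 3 of 0 min, and 138 and 115 without D310N replicate 1 or 3 of 240 min. At 360 min they are 121, 130 and 155 without WT replicate 1, 2 or 3 of 0 min, and 581, 509 and 372 without WT replicate 1, 2 or 3 of 360 min. They are 116 and 107 without D310N replicate 1 or 3 of 0 min, and 133 and 129 without D310N replicate 1 or 3 of 360 min. The calls of Atf3, Irg1 and Rin2 at 60 min and of Cxcl9 at 120 min hold in each of these.

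By lists, the immediate early and ERK-dependent genes rose less in D310N at 60 min (median -0.21, 2 of 25 smaller and 0 larger, 4 smaller adjusted over the list alone). At 240 min their LPS changes were lower in D310N (median -0.32, 7 smaller and 0 larger, 8 smaller adjusted over the list alone). For members that lay below their 0 min level by then, as Egr2 did, this is a deeper fall and not a lesser rise. Both list calls, at 60 and 240 min, hold with an estimated correlation (adjusted p = 0.000261 and 0.00401). A higher start in D310N is part of both differences. Relative to the WT mean, the list medians of the D310N libraries were 0.0519 to 0.225 at 0 min and -0.0837 to 0.0106 at 60 min. At 240 min they were -0.152 to -0.117. The LPS change of Egr2 was lower in D310N by -1.11 at 240 min and -0.93 at 360 min, from a level that was higher in D310N before LPS. Egr2 lay below its 0 min level at both times in both genotypes, so its fall was deeper in D310N. At 0 min its libraries lay at 9.42 to 10.09 (D310N) and 8.72 to 8.76 (WT). At 240 min they lay at 7.75 to 7.84 (D310N) and 7.78 to 7.89 (WT). Chemokine responses were smaller at 60 min (median -0.24, 1 of 19 smaller and 0 larger, 6 smaller adjusted over the list alone; adjusted p = 0.000261 with an estimated correlation). The 1 gene, Ccl7 (-0.44 ± 0.08), is named here after its values were seen. Responses of secondary transcription factors were smaller at 120 min (median -0.12, 4 of 24 smaller and 0 larger, 5 smaller adjusted over the list alone; adjusted p = 0.000379 with an estimated correlation), among them Bach1 (-0.69). Interferon-stimulated genes had a larger response at 240 min with a median of 0.19 (4 larger and 0 smaller, 13 adjusted over the list alone), a call that is lost with an estimated correlation (adjusted p = 0.296).

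The differences between genotypes resembled each other across times. Over the 15 pairs of times, which share no library, the differences of all tested genes correlated with a median r of 0.595 (0.506 to 0.836; Spearman median 0.541). The times may still not be independent. Deviations of D310N libraries that share number 1, 2 or 3 correlated across times by a mean of 0.208, 0.284 and 0.0697. Genes near the edited gene were called in a somewhat larger share than others, a difference that did not pass. Within 20 Mb of Tnip2 on chromosome 5, 93 of 172 genes (54.1%) differed on average, against 5473 of 11394 elsewhere (48.0%; odds ratio 1.27, 95% interval 0.931 to 1.75, Fisher's exact p = 0.124). Within 5 Mb 50 of 91 did (54.9%, exact p = 0.207). Among differences of at least 0.5 in size, 7 of 172 and 4 of 91 genes lay there (exact p = 0.362 and 0.349), and Abhd1 is the gene with the largest of them (2.16 on average). These shares concern the region as a whole. They do not decide whether single genes there, such as Abhd1 or Depdc5, differ because they lie near Tnip2.

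**Figure D4:**
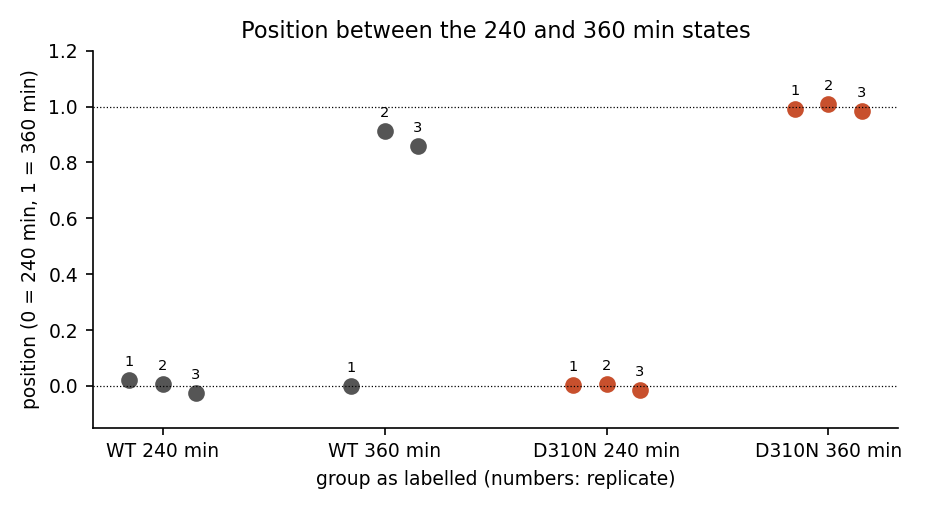
Position of each library labelled 240 or 360 min, from the 240 min mean of its own genotype (0, without the library itself) along the change from 240 to 360 min in the other genotype (1); the library labelled WT at 360 min, replicate 1, lies at 0.00135 and the other WT libraries of that time at 0.913 and 0.858.

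One library departs from its group. The library labelled WT at 360 min, replicate 1, lies at 0.00135 on a line from the WT mean at 240 min (0) along the change from 240 to 360 min in D310N (1), where the other 2 WT libraries labelled 360 min lie at 0.913 and 0.858. Tnip3, with a difference of -0.13 at 360 min and -0.32 without this library, is among the genes whose call depends on it, and directions at 360 min are drawn with it in the WT group. Without it, Tnfaip3 was lower in D310N by -0.23, Bcl3 by -0.39 and Ciita by -0.72, and all 3 calls were kept.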

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

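The tests for 3 patterns below were chosen only after the result was seen, apart from the test on the resident macrophage list; the splits of the samples were also computed after the counts were known.

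Of 129 genes named in the text, 37 passed a joint test that their LPS response differs between the genotypes, and all 37 also pass without the library labelled WT at 360 min, replicate 1. Without it 13 more pass: Plk1 (0.000319), Tnip1 (0.000976), Ier2 (0.00134), Tnip3 (0.00179), Gbp5 (0.00187), Ifnb1 (0.00327), Ccnb2 (0.00337), Rrm2 (0.00426), Il10 (0.00514), Socs3 (0.00515), Ciita (0.0188), Il6 (0.0209) and Abhd1 (0.023). What singled the 37 out is a test of the difference between genotypes itself. The share of 37 in 129 is no finding about the named genes, since some were chosen by this same test. Rin2, Ssfa2, Atf3, G530011O06Rik, Depdc5, Cxcl9, Dtd1, Gm5148, Irg1 and E2f8 had its smallest p-values, a ground for naming under the rule. Their passing was thus set in advance. Ccl7 and Slc1a2 were named after their values were seen. Among all 11656 tested genes 564 passed (4.8%). The joint adjusted p was 1.08e-12 for Rin2, 4.25e-09 for Ssfa2, 1.24e-07 for G530011O06Rik and Atf3, 1.64e-07 for Cxcl9 and Depdc5, 1.84e-07 for Dtd1, 6.64e-07 for Gm5148, and 1.33e-06 for Cxcl11, Irg1 and E2f8. It was 1.78e-05 for Bach1, 2.06e-05 for Klf4, 9.17e-05 for Dusp5, 0.000106 for Egr2, 0.00012 for Ifit3, 0.000253 for Ccnb1, 0.00029 for Ccl7, 0.000717 for Bcl3 and 0.000921 for Kif18b. Higher values were 0.0012 for Rsad2, 0.00146 for Slc1a2, 0.00227 for Nos2, 0.00448 for Mid1, 0.00493 for Ccl12, 0.0053 for Cxcl10, 0.00721 for Serpina3g, 0.0108 for Myc, 0.0114 for Fosl1, 0.0172 for Irf7, 0.0175 for Bcl2l11 and 0.0196 for Tnfsf9. The values nearest the threshold were 0.0246 for Jun, 0.0256 for Nfkbid, 0.0339 for Il23a, 0.0414 for Cebpa and 0.0424 for Tnfaip3.

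Leaving out 1 library ends 6 of these joint calls. That of Tnfaip3 is lost without any of 24 libraries (adjusted p up to 0.0949), that of Cebpa without any of 24 (up to 0.152) and that of Il23a without any of 15 (up to 0.0732). The call of Jun is lost without WT replicate 1 or 3 or D310N replicate 3 of 120 min (up to 0.0833), and that of Nfkbid without WT replicate 1 or 3 or D310N replicate 1 of 240 min (up to 0.0961). That of Tnfsf9 is lost without D310N replicate 1 or 3 of 360 min (up to 0.0664).

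The LPS response also differed for 3 lists with an estimated correlation. The immediate early and ERK-dependent genes had an adjusted p of 0.000261 at 60 min and 0.00401 at 240 min, the chemokines 0.000261 at 60 min, and the transcription factors of the secondary response 0.000379 at 120 min. Without the library labelled WT at 360 min, replicate 1, the 4 calls hold (0.00124, 0.0223, 0.00124 and 0.00547) and the cell cycle list also passes at 360 min (0.0166).

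Other splits of the libraries were fitted in the same way. For every count that sets 3 libraries against 3, the splits are too few (10) for a share under 0.05. The real count and the highest of the other splits were 1250 and 0, 1423 and 0, 1498 and 0, 2058 and 71, 1980 and 1, and 1903 and 1171 for the genotypes at the 6 times. For LPS they were 710 and 2, 4335 and 4, 7761 and 0, 9321 and 0, and 9367 and 542 in WT, and 774 and 0, 4489 and 0, 7461 and 0, 9224 and 0, and 9325 and 1 in D310N. The comparisons with 1171 and 542 both hold the library labelled WT at 360 min, replicate 1, which lies far from its group.

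For the average over the time course 1 of 100 splits, the real one, gave as many genes (5604, highest other 1087), so that chance can be excluded under a shuffling of libraries within each time; with the sets of libraries that share genotype and number kept whole the splits are too few (1 of 10, highest other 518). For differing responses 2, 2, 2 and 3 of 100 splits gave as many genes at 60, 120, 240 and 360 min, the real one included. The counts, with the highest other split, were 8 and 1969, 109 and 2126, 227 and 850, and 234 and 1717, and the joint test gave 564 and 1843 with 2 of 100. These splits cannot exclude chance for the responses. A shuffling of libraries within each time also mixes the constant difference between genotypes into the spread within groups. It therefore asks whether there is any genotype difference, and not whether the responses differ. With the sets that share genotype and number kept whole, splits of the responses were not fitted, and 10 would be too few. The other splits that call several times the real count point to a structure of the samples. At 60, 120, 240 and 360 min 1, 1, 1 and 2 of 99 random splits parted the libraries by genotype one way at 0 min and the other way round at that time, and they are the splits that gave as many genes (the highest count of the rest was 1, 20, 5 and 16). At 30 min the real count is 0, which all 100 of 100 splits reach whatever they hold (highest other 1), so that they decide nothing.

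The library labelled WT at 360 min, replicate 1, lies far from the other WT libraries of that time. It differs from the WT libraries of 240 min by a root mean square of 0.22, 0.226 and 0.216, close to the 0.188 to 0.205 among these, and from replicates 2 and 3 of its own group by 0.399 and 0.373. A swap of labels with a library labelled 240 min is argued against, as the highest of those 6 lies at 0.0196 on the line from 240 min (0) to 360 min (1). Fewer reads are argued against by the correlation across genes of its deviation with the change from 240 to 360 min (-0.737). Its position of 0.00135 is what cells taken at about 240 min would give, so a wrong label or an early harvest may be the cause, and no biological explanation was tested.

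Several of the genes with the largest difference between D310N and WT lie close together on chromosomes 1, 2 and X. The 19 top genes, without G530011O06Rik, hold 4 pairs within 5 Mb. By comparison, 10000 random sets hold a median of 1 (95th percentile 3, permutation p = 0.028). This p was computed on the genes in which the pattern was seen, so it restates the pattern and is no separate support. The pairs among Slc1a2, Rag1 and Depdc7 also share genes and are not separate events. Reads shared between overlapping genes, as in Mid1 and G530011O06Rik, the pair on chromosome X, are not the whole cause, since 4 pairs that do not overlap are left: Slc1a2 and Rag1 (1.02 Mb apart), Slc1a2 and Depdc7 (2.06 Mb), Rag1 and Depdc7 (3.08 Mb), and Fn1 and Ptprn (3.66 Mb). Slc1a2 (-1.75 on average), Rag1 (-1.75) and Depdc7 (-1.07) were named after their values were seen. Of the 5 pairs, the overlapping one included, 0 hold a gene within 20 Mb of Tnip2 on chromosome 5. Since the pattern was drawn on chromosomes 1, 2 and X, this count was set in advance. It shows only where the pairs lie and is no test of chromosome segments of another strain beside Tnip2. Other inherited differences between the lines, away from Tnip2, stay open, as among tested genes within 5 Mb of the paired genes, without the 20 top genes, 54 of 94 differed on average against 5492 of 11453 elsewhere (odds ratio 1.47, 95% interval 0.954 to 2.27, Fisher's exact p = 0.0777).

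Interferon-stimulated and cell cycle genes were lower in D310N. The authors' normalisation, as a scaling between libraries, is argued against as the whole cause. Quantile normalisation moves 4234 of 11656 genes by over 0.05 at 0 min and leaves both lists called. Their medians are then -0.35 and -0.75, below 0 by over 1 SD of their members (0.173 and 0.383). The unnamed transformation to log2 values was not tested in this way. A lower share of macrophages as the whole cause of the interferon difference is argued against by the resident macrophage list. Its median of -0.026 lies above that of the interferon list (-0.31 on average) by over 1 SD of its members (0.163). A smaller fall of that share is not excluded by this test, and the cell cycle list was not compared in this way. Neutrophil and stromal genes were higher on average (4 and 5 of 6 genes, medians of 0.30 and 0.37) and dendritic cell genes were not (-0.04). A rise of neutrophils or stromal cells alone therefore stays open. However, only 6 of the 17 neutrophil and 6 of the 15 stromal genes in the deposited table passed the filter. Both medians thus rest on a minority of the markers. Differences between cultures unrelated to genotype cannot be told apart from genotype, because the replicates are not stated to be separate cultures, although the list medians averaged over the times differ by -0.30 and -0.58, which is 10.8 and 7.78 times the SD between the 3 sets of libraries per genotype that share a number. An effect of the D310N form on both sets stays open as a biological explanation that was not tested.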

How the results depend on the processing

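The fits without 4 libraries that stand apart and with a block of replicate number within genotype were chosen after the data were seen. Library weights raise these counts: 3458, 2909, 3457 and 3548 genes differ between genotypes at 0, 30, 60 and 240 min, 1454 and 1904 change with LPS at 30 min in WT and D310N, and responses differ for 3, 67 (36 larger, 31 smaller), 363, 1370 and 1005 genes from 30 to 360 min and 1821 jointly. With only the libraries compared, 1896, 2387 and 12 genes differ between genotypes at 0, 60 and 360 min, 1186 change with LPS at 30 min in D310N, and responses differ for 28 (15 larger, 13 smaller), 565 and 15 (10 and 5) at 60, 240 and 360 min. Without the 4 libraries that stand apart responses differ for 24, 238, 425 and 513 genes from 60 to 360 min and 962 jointly. Quantile normalisation gives 1219 genes for LPS in WT at 30 min and 13 for responses at 60 min. A replicate block within genotype gives 350 responses at 240 min. The replicate block over all libraries ended 2 calls of named genes and added 4, among them Tnip2 at 360 min between genotypes (adjusted p = 0.0387). The replicate number as a correlated effect ended 6 and added 2. Neither the block nor the correlated effect moved a gene count by over 1.5 times. The cause of these shifts was not tested.

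Leaving out each library in turn gives 716 to 1331, 861 to 1500, 986 to 1459, 1510 to 1897, 1190 to 1847 and 1115 to 2346 genes between genotypes at the 6 times and 5334 to 6099 on average. For LPS it gives 504 to 693, 3784 to 4051, 7349 to 7374, 9039 to 9080 and 9056 to 9366 in WT, and 550 to 639, 3822 to 4138, 6901 to 7267, 8871 to 8962 and 9009 to 9090 in D310N. Responses range from 0 to 1, 4 to 7, 56 to 96, 92 to 215 and 107 to 581, and 432 to 1218 jointly. The cause of the higher counts was not tested.

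With an estimated correlation, fewer lists are called: 1, 2, 3, 4, 2, 0 and 2 in place of 8, 8, 9, 13, 9, 8 and 10 between genotypes at the 6 times and on average, 9 and 8 in place of 14 and 15 for LPS at 30 min in WT and D310N, and 0, 2, 1, 1 and 0 in place of 5, 9, 8, 8 and 6 for responses. This follows from its construction, since members that move together widen the error of their mean.

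Quantile normalisation reverses 28 LPS changes of named genes in WT. At 60 min they are Atp5b (-0.18), Atp5a1 (-0.15), Ctsz (-0.27), Hsp90aa1 (-0.014), Rps14 (-0.090), Rplp0 (-0.27), Rps6 (-0.19) and Rpl27 (-0.11), and at 120 min Atp5a1 (-0.17), Ctsz (-0.21), Hsp90aa1 (-0.16), Rps14 (-0.20), Rplp0 (-0.31), Rpl27 (-0.15) and Rpl5 (-0.26). At 240 min they are Hspa8 (-0.42), Rpl27 (-0.33), Rpl19 (-0.49), Rpl7 (-0.55), Pf4 (-0.022) and Ddx3y (-0.17), and at 360 min Npc2 (-0.12), Hspa5 (-0.066), Rpl27 (-0.31), Rpl19 (-0.54), Rpl7 (-0.57), Pf4 (-0.065) and Ddx3y (-0.13). The cause was not tested.

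Of the values of named genes, quantile normalisation kept 1165 in direction and side of the threshold, ended 58 calls and added 8. Trimmed mean scaling kept 1244 and ended 15, library weights kept 1198, ended 22 and added 39, and only the libraries compared kept 1027, ended 93 and added 18. A fit with no filter kept 1228 and ended 31, one without the 4 libraries that stand apart kept 1194, ended 52 and added 13, and pseudocounts of 0.5 and 1 kept 1258 and ended 1. A pseudocount of 8 and a robust empirical Bayes step each kept 1253 and ended 6, and a filter of 50 in at least 3 libraries kept all 1212 values it could give. Leaving out 1 library kept 11062 values, ended 585 calls and added 17. The median of all genes moved by at most 0.0846 (quantile) and 0.0393 (trimmed mean). Read depth is unknown, so what it limits cannot be given.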

Other observations

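These values were noticed in the data and carry no test. The ribosomal RNA entry Rn45s lies 4.22, 3.80 and 2.38 above its median over the libraries (log2) in the libraries labelled WT at 30 min, replicate 3, D310N at 30 min, replicate 3, and D310N at 240 min, replicate 1. The library labelled WT at 360 min, replicate 1, deviates from its group mean by 2.22 times the median of all libraries. These are the 4 libraries that stand apart. In the 2914 tested genes with the highest values, replicate 1 of WT at 360 min differs from the mean of replicates 2 and 3 by a root mean square of 0.281, and these from each other by 0.115.

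Pira1, an immunoglobulin-like receptor gene, reaches 18.98 on the log2 scale in the library labelled D310N at 60 min, replicate 3, and at most 0.73 in any other library, and was not tested. Deviations from the group means of libraries that share genotype and number correlate across times by a mean of 0.208, 0.284 and 0.0697 for D310N 1, 2 and 3, and by -0.0166, 0.0206 and 0.0225 for WT.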
